A study of Mus musculus with 12 samples.

How the data were processed

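Poly-A RNA of B cells purified from the spleens of WT and Fcmr KO mice was measured in 12 libraries, 3 for each genotype at 1 h and at 6 h of exposure to 10 µg/mL of F(ab')2 anti-IgM. The deposited values are FPKM, fragments scaled by transcript length and by the size of the library, with a column for each library and 55487 genes. FPKM is the unit given by the table's name, and the authors do not state the gene annotation or the gene length used. The genome build mm10, the aligner STAR and the counting tool HTSeq are named per the submitters' processing notes, without versions. All 12 columns were used and 0 columns were left out. Columns were assigned to groups by the sample titles and the column names given with them. Of the genes, 55141 have a symbol and 55227 a position in the GENCODE annotation of the mouse, release vM21, which was used for symbols and positions, and 27552 are 0 in all libraries.

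Multiplied by an annotated transcript length, the values of 99.11% of the tested genes were whole multiples of a library's smallest step (tolerance 0.001). With lengths solved from the values 99.98% were recovered as whole fragments. The library totals found in this way, 19260751 to 24058818 fragments, are the depth. The recovered fragments of all genes summed to 100.11% to 100.35% of those totals. A count of 3 fragments on a transcript of 2 kb is 0.0623 to 0.0779 FPKM, a floor for counting error alone. Replicates differed by more than counting error, with a chi-square per degree of freedom of 7.52 to 31.61 between libraries of a group.

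Values were tested as log2(FPKM + 1) with limma, with 1 mean for each of the 4 groups, a variance trend in the moderation, two-sided tests and Benjamini-Hochberg adjustment over the 11841 genes with a mean of at least 1 FPKM over the 12 libraries. A gene was called at an adjusted p under 0.05. The comparisons were KO against WT at 1 h and at 6 h, 6 h against 1 h in WT and in KO, and the difference between the genotypes in the change over time. Log2 fold changes are KO over WT or 6 h over 1 h, and their SE come from limma. A test for counts had been foreseen only for a table of counts and was not used, as the table holds FPKM. Fcmr was also compared by an exact two-sided permutation test of 3 against 3. The comparisons, tests, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined.

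The named genes of each comparison were Fcmr and up to 8 higher and 8 lower genes with the largest log2 fold change among called genes whose 3 libraries of one group all lay above the 3 of the other. Where none passed in a direction, the 5 with the smallest p were taken and said not to pass. Up to 4 members with the smallest p were taken from each gene list described. Predicted genes without a proper symbol, pseudogenes, immunoglobulin and T cell receptor segments, histone genes and genes linked to sex were exempt. Genes within 5 Mb of Fcmr, genes shared by both times and the V segments were singled out after their values were seen, as were S100a8 and mt-Co2.

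The 33 gene lists were BCR signalling components, BCR inhibitory receptors and phosphatases, immediate early genes, NFAT and calcium responsive genes, NF-kB target genes, B cell activation markers, MYC and ribosome biogenesis, G1/S cell cycle, glycolysis, amino acid transport and tRNA charging, cholesterol synthesis, ER stress and unfolded protein response, heat shock genes, MHC class II presentation, interferon stimulated genes, apoptosis and survival, quiescence and FOXO targets, markers of follicular, marginal zone, B-1, transitional, plasma and germinal center B cells, markers of T cells, NK cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, platelets and megakaryocytes, and stromal and endothelial cells, mitochondrially encoded genes, and Fc receptors and neighbours of Fcmr. Of the 17 stromal and endothelial markers 0 reached the filter, and that list was not tested. The other 32 lists, each with at least 3 genes tested, were tested with camera at a preset correlation between genes of 0.01 and adjusted over the 32 lists. Camera was repeated with the correlation estimated from the data, and fry, which tests whether the genes of a list move one way on balance, was run beside it. Counts of called members are given over all genes and adjusted over the list alone.

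Whether replicate numbers pair libraries was checked on deviations from the group means over the tested genes. Libraries of the same genotype and number at 1 h and 6 h correlated at 0.338 to 0.547 in WT and 0.365 to 0.476 in KO, against -0.368 to 0.017 and -0.279 to -0.132 for other numbers. Over immunoglobulin V genes the same-number values were 0.853 to 0.867 and 0.896 to 0.905. Numbers therefore pair libraries across the times within a genotype. WT and KO libraries of the same number correlated at -0.15 to 0.248 at 1 h and -0.075 to 0.01 at 6 h, within the range of other numbers, and are not paired.

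The fit was tested on simulated data with 200 changed genes per comparison and with the means, spreads and totals of the libraries. Of 100 genes changed 1.5-fold it recovered 77 (KO against WT at 1 h), 74 (at 6 h), 80 (time in WT), 72 (time in KO) and 60 (difference between genotypes), and of 100 changed 2-fold 87, 89, 86, 91 and 78. Among the unchanged genes 9, 9, 10, 8 and 11 were called. With the immediate early genes changed 1.5-fold, camera called that list and 1 other in each comparison. Values were drawn independently for each gene and library, without correlation between genes or between same-number libraries. How often camera calls unchanged lists in the measured data was therefore not tested by the simulation.

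The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, rescaling to TPM, quantile normalization, leaving out immunoglobulin and mitochondrial genes, a robust spread, array weights, the replicate number as a block, genotype and number as a block, each of the 12 libraries left out, the 6 compared libraries alone, and a threshold of 1.5-fold. Array weights fitted gene by gene, both WT libraries numbered 3 left out, the mouse as a random effect (within-mouse correlation 0.215) and voom on recovered fragments were chosen after seeing the data. Values were computed with R 4.3.3, limma 3.58.1, statmod 1.5.0, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.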

Results

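RNA was sequenced from B cells purified from the spleens of wild-type (WT) mice and of mice lacking Fcmr (KO), the gene of the Fc receptor for IgM. The labels call the cells naive. The cells were exposed to F(ab')2 anti-IgM, an antibody fragment that crosslinks the B cell receptor (BCR), at 10 µg/mL and were collected after 1 h or 6 h. The 12 libraries form 4 groups of 3, WT and KO at each time. Each library held between 19260751 and 24058818 fragments, with 20311 to 21225 genes above 0 and 11510 to 11822 genes at 1 FPKM or more. At this depth 3 fragments on a transcript of 2 kb correspond to 0.0623 to 0.0779 FPKM. The labels call the libraries biological replicates without naming the animals, so p-values measure the spread between these libraries. None of the 12 libraries came from cells without anti-IgM, and all values refer to stimulated cells. Changes from 1 h to 6 h therefore cannot be divided between stimulation, time in culture and a changing mix of cells.

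Time after stimulation separated the libraries most, with 83% of the variance on the first principal component. The second component held 5.3%. On it both WT libraries numbered 3 (-5.91 at 1 h and -6.28 at 6 h) lay among the KO libraries (-2.23 to -15.79) and apart from the other WT libraries (10.77 to 20.97). A transcript of another blood cell moved in the same way. S100a8, a neutrophil protein gene, stood at 283, 137 and 14.2 FPKM in WT replicates 1, 2 and 3 at 1 h and at 22.3, 6.91 and 10.0 FPKM in the KO replicates. T cell, NK cell and macrophage markers did not follow it, since their mean log2(FPKM + 1) in WT replicate 3 at 1 h (2.635, 3.883 and 3.949) lay above those of all KO libraries (at most 2.491, 3.312 and 3.497).

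Fcmr (ENSMUSG00000042474, mm10 chromosome 1, 130865669 to 130880791) was lower in KO cells at both times. Its level was 49.3 ± 0.664 FPKM in KO and 373.1 ± 18.5 FPKM in WT cells at 1 h (SD, n = 3 each), or 13.2% of WT. At 6 h it was 44.05 ± 2.06 FPKM in KO and 383 ± 16.9 FPKM in WT cells, or 11.5% of WT. The log2 fold changes were -2.89 (SE 0.05, limma adjusted p = 2.19e-10) and -3.09 (SE 0.05, adjusted p = 1.1e-10). All 3 KO libraries lay below all 3 WT libraries at each time, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. The KO libraries held 1501 to 1754 Fcmr fragments and the WT libraries 11587 to 14608. A value summed over the gene does not say which exons the remaining fragments cover. Fcmr differed little between the times, by 0.04 in WT (adjusted p = 0.497) and by -0.16 in KO cells (adjusted p = 0.0125).

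**Figure D1:**
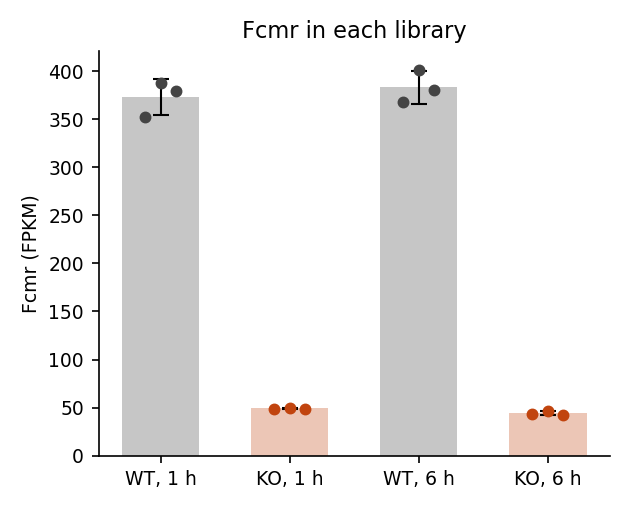
Fcmr level in FPKM (y axis) in the 4 groups (x axis). Bars are means from 0, error bars the SD and points the 3 libraries of each group, with the KO libraries at 42.6 to 50.1 FPKM and the WT libraries at 352 to 401 FPKM.

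By its title, the series addresses whether BCR signalling triggered by antigen is reduced in B cells without Fcmr. At 1 h of stimulation, 62 of the 11841 genes tested differed between KO and WT cells (limma, adjusted p under 0.05), 10 of them higher and 52 lower in KO cells. Ctse, which encodes the aspartic protease cathepsin E, was the most increased of the named genes, at 134 ± 6.51 FPKM in KO against 38.5 ± 18.3 FPKM in WT cells (SD, n = 3 each; log2 fold change 1.91, SE 0.33, adjusted p = 0.0313). Cxcr4, the receptor for the chemokine CXCL12, was higher by 0.79 (SE 0.07), Shank1 by 0.48, Cd72, an inhibitory coreceptor of B cells, by 0.33 and the caspase gene Casp4 by 0.31. Map3k19 was at 0.0832 ± 0.0427 FPKM in KO and 6.28 ± 0.684 FPKM in WT cells (log2 fold change -2.74, SE 0.10), and Tsga13 changed by -1.62. The KO level of Map3k19 was near that of 3 fragments, so the size of its fold change depended on the pseudocount and scale (-2.67 to -6.28 over the alternatives, the last with voom on recovered fragments), and it was called in all 26 of them. The aminopeptidase gene Rnpep (-1.12), the scavenger receptor genes Cd36 (-0.92) and Marco (-0.86), the iron exporter gene Slc40a1 (-0.88) and the ubiquitin-conjugating enzyme gene Ube2t (-0.85) were also lower. For all 62 genes the 3 libraries of one genotype lay above the 3 of the other, which held for 14.8% of all genes tested, where chance gives 10%.

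Genes of the signalling pathway below the BCR gave no call at 1 h. Of 34 BCR signalling components, 0 passed over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05, limma), and their median log2 fold change was 0.001 (camera adjusted p = 0.691). The 4 with the smallest p were the adaptor gene Blnk (-0.13), Bcl10 (-0.15), Akt1 (-0.13) and Pik3ap1 (0.15). Of 26 inhibitory receptors and phosphatases, Cd72 was called, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.981). The immediate early genes, transcription factors and phosphatases induced within minutes of stimulation, lay lower in KO cells. Of 38, 33 had a negative fold change and the median was -0.167, with Jun at -0.42, Egr1 at -0.37, Atf3 at -0.48 and Dusp5 at -0.25. None of them passed over all genes (16 at an unadjusted p under 0.05, limma) and 7 were lower adjusted over the list alone. The list passed camera (adjusted p = 1.4e-07), with adjusted p = 0.365 with an estimated correlation. Its mean log2(FPKM + 1) was 6.131, 6.248 and 6.364 in WT replicates 1, 2 and 3 and 6.048 to 6.131 in the KO libraries. WT replicate 1 thus stood level with the highest KO library. Among 21 NFAT and calcium responsive genes, the chemokine gene Ccl3 was lower (-0.63, SE 0.10) and 2 were lower adjusted over the list alone. The call of Ccl3 ended without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 3 of 1 h (adjusted p = 0.099, 0.0914, 0.0966 and 0.0808). Ccl3 was also the called gene among 28 B cell activation markers, where 3 were lower adjusted over the list alone. Of 33 NF-kB target genes 0 were called (5 at an unadjusted p under 0.05), with 1 lower adjusted over the list alone. These last 3 lists did not pass camera (adjusted p = 0.691, 0.226 and 0.602).

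Lists of growth and metabolism shifted by small amounts at 1 h. Mcm6, a subunit of the replicative helicase, was the called gene of the G1/S list (-0.54, SE 0.09), and its call ended without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 of 1 h or KO replicate 1 of 6 h (adjusted p = 0.0818, 0.116, 0.106, 0.0984 and 0.0529). Of its 32 members 31 had a negative fold change (median -0.172, camera adjusted p = 7.02e-07), and 1 was lower adjusted over the list alone. Their mean log2(FPKM + 1) was 3.723, 3.624 and 3.363 in WT replicates 1, 2 and 3 and 3.208 to 3.444 in the KO libraries, so WT replicate 3 lay among the KO libraries, as it did for neutrophil markers (2.031; KO 1.573 to 2.286) and erythroid markers (3.369; KO 3.365 to 5.012). Glycolysis genes had a median of -0.121 with Slc2a3 at -0.29 and Hk2 at -0.27 (limma, 0 of 21 called, 5 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone, camera adjusted p = 0.000417). Their mean in WT replicate 3 (4.745) lay just above the KO libraries (4.647 to 4.735) and apart from WT replicates 1 and 2 (4.894 and 4.848). The adjusted p with an estimated correlation was 0.374 for G1/S and 0.365 for glycolysis. Cholesterol synthesis genes had a median of 0.121, with Cyp51 and Idi1 each at 0.28 (camera adjusted p = 1.73e-06, adjusted p = 0.365 with an estimated correlation). For this list too WT replicate 3 (3.248) lay among the KO libraries (3.363, 3.219 and 3.246) and apart from WT replicates 1 and 2 (3.023 and 3.121). MYC and ribosome biogenesis genes had a median of -0.056 (camera adjusted p = 0.0309), and genes of ER stress and the unfolded protein response one of 0.094 (camera adjusted p = 0.0171). With an estimated correlation these gave adjusted p = 0.805 and adjusted p = 0.685, and without WT replicate 1, KO replicate 2 or KO replicate 3 of 1 h the MYC list did not pass (adjusted p = 0.643, 0.626 and 0.222). Its mean in WT replicate 3 (4.974) and in WT replicate 2 (5.016) lay among the KO libraries (4.921 to 5.086). The ER stress list did not pass without WT replicate 3 (adjusted p = 0.229) or KO replicate 3 (0.499) of 1 h, and its mean in KO replicate 3 (5.985) stood above KO replicates 1 and 2 (5.788 and 5.714), which lay within the WT range (5.658 to 5.807). In the cholesterol, MYC and ER stress lists 0 members were called over all genes or adjusted over the list alone (7, 3 and 6 at an unadjusted p under 0.05, limma). Apoptosis genes (camera adjusted p = 0.0693), genes of quiescence with Cxcr4 among them (0.338), amino acid transport and tRNA charging (0.268), heat shock genes (0.182), MHC class II genes (0.484) and mitochondrially encoded genes (0.691) did not pass.

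Markers of marginal zone B cells and of macrophages were lower in KO cells at 1 h. Of 19 marginal zone markers 4 were lower, namely Pik3r4 (-0.51), Cd36 (-0.92), Myof (-0.67) and the sphingosine receptor gene S1pr3 (-0.57), and 12 were lower adjusted over the list alone. Their median was -0.366 (camera adjusted p = 2.52e-13, adjusted p = 0.0155 with an estimated correlation). Of 21 macrophage markers 7 were lower, among them the phagocytic receptor genes Axl (-0.65) and Mertk (-0.66), Slc40a1 (-0.88) and the complement gene C1qc (-0.70), and 19 were lower adjusted over the list alone. Their median was -0.631 (camera adjusted p = 1.03e-22, adjusted p = 0.0155 with an estimated correlation). Other blood cell lists also had negative medians, though WT replicate 3 lay among the KO libraries for neutrophil and erythroid markers. The median was -1.818 for 13 neutrophil markers, -0.331 for 16 T cell markers, -0.302 for 15 NK cell markers, -0.603 for 15 erythroid markers and -0.234 for 6 platelet markers, of which Clec1b was called. These lists passed camera (adjusted p = 8.75e-07, 1.59e-05, 1.44e-05, 0.0135 and 0.0287), with adjusted p = 0.365 with an estimated correlation for all of them except the erythroid list (0.722). Without 1 library of 1 h the camera call ended for erythroid markers (WT replicates 1 and 2 and KO replicates 2 and 3, adjusted p = 0.449, 0.14, 0.301 and 0.0791), platelet markers (WT replicate 1 and KO replicate 2, 0.166 and 0.137), NK cell markers (WT replicate 3, 0.0541) and interferon stimulated genes (WT replicate 1, 0.166). Adjusted over the list alone 3 neutrophil, 7 T cell, 3 NK cell, 0 erythroid and 1 platelet markers were lower, and 1 T cell marker was higher. Of 31 interferon stimulated genes all 31 had a negative fold change (median -0.221, 0 called, 4 at an unadjusted p under 0.05, camera adjusted p = 0.000499, adjusted p = 0.685 with an estimated correlation). Isg15 followed the neutrophil transcripts, at 27.3, 17.1 and 7.4 FPKM in WT replicates 1, 2 and 3 and at 8.78, 6.11 and 6.09 FPKM in the KO replicates.

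The remaining B cell lists differed less at 1 h. Plasma cell markers had a median of 0.121 with 14 of 15 positive and 0 called (3 at an unadjusted p under 0.05), and passed camera (adjusted p = 0.0122, adjusted p = 0.569 with an estimated correlation). Their mean log2(FPKM + 1) was 4.961 in KO replicate 3, with KO replicates 1 and 2 (4.594 and 4.561) within the WT range (4.467 to 4.663), and the list did not pass without KO replicate 3 (adjusted p = 0.298) or WT replicate 3 (0.085) of 1 h. B-1 cell (median 0.083, camera adjusted p = 0.0573), follicular (0.526), transitional (0.883), germinal center (0.691) and dendritic cell markers (0.334) did not pass. The follicular list had a median of -0.031 and a mean of 0.009. The list of Fc receptors and neighbours of Fcmr held 2 lower genes, Fcmr and Rassf5 (-0.30), and 4 adjusted over the list alone (camera adjusted p = 0.0184, adjusted p = 0.365 with an estimated correlation and 0.052 without WT replicate 2 of 1 h). The knocked-out gene Fcmr is itself a member, so part of this shift was built in (list median -0.056, mean -0.299). The list is still counted among those that passed camera. In all, 16 of 32 lists passed camera at 1 h, 3 up and 13 down (1 up and 11 down without KO replicate 3), and the marginal zone and macrophage lists did so with an estimated correlation too. Without a single library the count of 62 genes became 39 (WT replicate 1), 31 (WT replicate 2), 142 (WT replicate 3) or 30 (KO replicate 1), and it was 21 when the 6 libraries of 1 h were fitted alone, 115 with no filter, 32 at a mean of at least 5 FPKM, 191 without both WT libraries numbered 3 (an alternative chosen after seeing the data) and 40 for changes of at least 1.5-fold. The call of Ctse ended in 12 of 27 alternatives, that of Marco in 12 of 26, C1qc in 9 of 27, Mcm6 in 7 of 27, Clec1b in 7 of 26, Shank1 in 6 of 26, Ccl3 and Rassf5 in 5 of 27, Mertk in 5 of 26, Slc40a1 in 4 of 27 and Casp4 in 3 of 27. Those of Cd72, Ube2t, Pik3r4, Myof, S1pr3 and Axl ended when the 6 libraries of 1 h were fitted alone.

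At 6 h of stimulation 27 genes differed between KO and WT cells (limma, adjusted p under 0.05), 16 higher and 11 lower in KO cells. Ctse stood at 50.1 ± 3.62 FPKM in KO and 9.98 ± 2.70 FPKM in WT cells (SD, n = 3 each; log2 fold change 2.25, SE 0.33, adjusted p = 0.0235). Cxcr4 was higher by 0.76 (SE 0.07), the tyrosine phosphatase gene Ptpn7 by 0.50, Ikbip by 0.44, the proton channel gene Hvcn1 by 0.41, Csrp1 by 0.40, the epoxide hydrolase gene Ephx1 by 0.39 and Manea by 0.35. Among genes lower in KO cells were Rnpep (-1.17), Slc40a1 (-1.09), Mcm6 (-0.87), the insulin-degrading protease gene Ide (-0.84), Fgfbp3 (-0.79), the survival kinase gene Pim1 (-0.60, SE 0.06) and Dusp5 (-0.55, SE 0.07), a phosphatase that acts on ERK. The libraries of the genotypes did not overlap for any of the 27 genes, against 15.1% of all genes tested and 10% by chance.

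Several lists of activation lay lower in KO cells at 6 h. Of 33 NF-kB target genes 27 had a negative fold change, the chemokine receptor gene Ccr7 was called (-0.44, SE 0.07) and 2 were lower adjusted over the list alone. The next smallest p were those of Nfkbid (-0.46), Ccl5 (-0.34) and Icam1 (-0.22), which did not pass over all genes. The median was -0.097 (camera adjusted p = 3.87e-07, adjusted p = 0.111 with an estimated correlation). Mean log2(FPKM + 1) of the NF-kB list was 4.877 to 4.954 in the KO libraries and 5.039 to 5.059 in the WT libraries. Pim1 was the called gene of 28 apoptosis and survival genes, with Pim2 at -0.30, the proapoptotic gene Pmaip1 at -0.21 and Bcl2, which opposes apoptosis, at 0.30. There 3 were lower adjusted over the list alone (median -0.05, camera adjusted p = 0.00915, adjusted p = 0.111 with an estimated correlation). Dusp5 was called among 38 immediate early genes, with 3 lower adjusted over the list alone and Gadd45b at -0.47, Jun at -0.36 and Atf3 at -0.34 (median -0.037, camera adjusted p = 0.0238, adjusted p = 0.653 with an estimated correlation, and 0.116 and 0.0725 without WT replicate 2 and KO replicate 1 of 6 h). Among 28 B cell activation markers Ccr7 was called and 2 were lower adjusted over the list alone (median -0.085, camera adjusted p = 0.00599, adjusted p = 0.266 with an estimated correlation). The NFAT and calcium responsive genes did not pass (median 0.06, 12 of 21 positive, camera adjusted p = 0.518), with 0 called (limma, 5 at an unadjusted p under 0.05) and 1 higher adjusted over the list alone. MHC class II genes lay higher, with 12 of 14 positive and a median of 0.196. None was called (7 at an unadjusted p under 0.05, limma) and 6 were higher adjusted over the list alone, with the transactivator gene Ciita at 0.46, H2-DMb2 at 0.28, H2-Oa at 0.36 and H2-DMa at 0.27 (camera adjusted p = 4.57e-05, adjusted p = 0.403 with an estimated correlation). The mean log2(FPKM + 1) of MHC class II genes in WT replicate 2 (7.219) lay among the KO libraries (7.205 to 7.342). WT replicates 1 and 3 stood at 7.055 and 6.991. BCR signalling components had 0 called genes (3 at an unadjusted p under 0.05) and a median of 0.049 (camera adjusted p = 0.0501), with Pik3ap1 at 0.25, Blk at 0.15 and Prkcb at 0.19. Inhibitory receptors and phosphatases had 0 called genes (7 at an unadjusted p under 0.05) and 2 higher adjusted over the list alone, with Cd5 at 0.39 and Cd22 at 0.30 (camera adjusted p = 0.179).

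**Figure D2:**
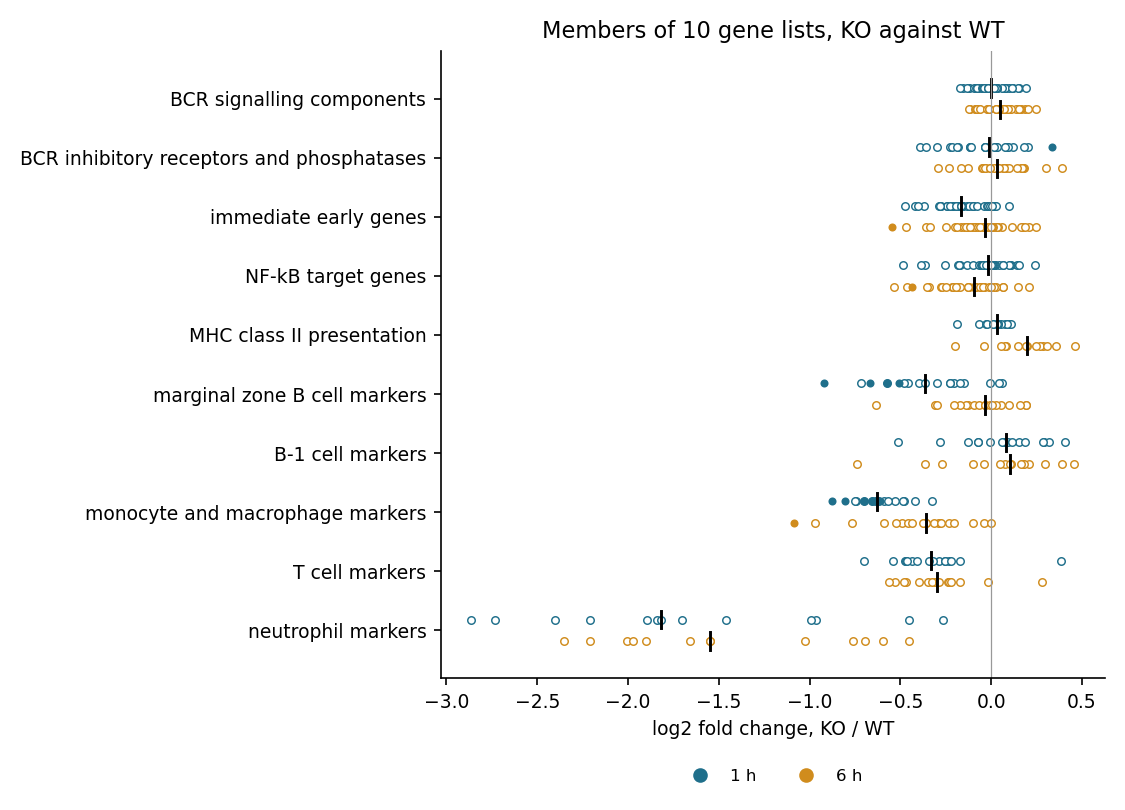
Log2 fold change of KO against WT (x axis) for each tested member of 10 gene lists (y axis), at 1 h and at 6 h. Points are genes, filled where the adjusted p is under 0.05, and black ticks are list medians, which are 0.001 at 1 h for BCR signalling components and -0.631 for macrophage markers.

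Lists of growth lay lower in KO cells at 6 h by small amounts. The medians were -0.083 for MYC and ribosome biogenesis genes, -0.054 for G1/S genes with Mcm6 lower, -0.114 for heat shock genes and -0.043 for amino acid transport and tRNA charging. These lists passed camera (adjusted p = 0.000146, 0.00935, 0.0072 and 0.0486), with adjusted p = 0.601, 0.672, 0.587 and 0.672 with an estimated correlation. Mean log2(FPKM + 1) in WT replicate 3 lay among the KO libraries for MYC genes (6.531, KO 6.434 to 6.534). So it did for G1/S genes (3.463, KO 3.416 to 3.475). It lay below the KO libraries for amino acid genes (5.886, KO 5.893 to 5.913) and above them for heat shock genes (7.296, KO 7.126 to 7.261). The call of the amino acid list ended in 13 of 28 alternatives, among them WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3 of 6 h left out (adjusted p = 0.0872, 0.522, 0.0726 and 0.138), and that of the G1/S list without WT replicate 1 or 2 of 6 h (0.0872 and 0.069). Macrophage markers again lay lower, with Slc40a1 called, 10 of 21 lower adjusted over the list alone and a median of -0.361 (camera adjusted p = 3.68e-13, adjusted p = 0.111 with an estimated correlation). Neutrophil markers (median -1.549), T cell markers (-0.3), NK cell markers (-0.245) and interferon stimulated genes (-0.109) also had negative medians. For these the camera adjusted p was 3.12e-08, 3.74e-06, 9.25e-06 and 0.0175, with 0.403, 0.403, 0.403 and 0.692 as the adjusted p with an estimated correlation. The interferon list did not pass without WT replicate 1 or 3 or KO replicate 1 or 3 of 6 h (adjusted p = 0.12, 0.395, 1 and 0.253). Interferon and neutrophil lists did not move together at 6 h. KO replicate 2 had the highest mean log2(FPKM + 1) of interferon genes (3.171) and the lowest of neutrophil markers (1.065). S100a8 stood at 124, 88.7 and 4.97 FPKM in WT replicates 1, 2 and 3 and at 13.2, 4.85 and 5.05 FPKM in the KO replicates. Marginal zone markers did not pass at 6 h (median -0.034, camera adjusted p = 0.118). In all, 14 lists passed camera, 1 up and 13 down, and 0 did so with an estimated correlation. With fry 4 lists passed, all down. These were NF-kB target genes (fry adjusted p = 0.0281), apoptosis and survival (0.0281), macrophage markers (0.022) and Fc receptors and neighbours of Fcmr (0.000183). The last holds Fcmr itself and did not pass camera (adjusted p = 0.0501). The count of 27 genes became 12 without WT replicate 1, 17 without WT replicate 2 and 16, 14 and 15 without KO replicates 1, 2 and 3, and it was 10 from the 6 libraries of 6 h alone, 64 without both WT libraries numbered 3 (chosen after seeing the data) and 15 for changes of at least 1.5-fold. The larger part of the called genes turned from higher to lower in KO without WT replicate 1 (5 higher and 7 lower), WT replicate 3 (9 and 18), KO replicate 2 (6 and 8) or KO replicate 3 (4 and 11) of 6 h, without WT replicate 2 (9 and 11) or KO replicate 1 (8 and 10) of 1 h, from the 6 libraries alone (4 and 6), for changes of at least 1.5-fold (7 and 8) and without both WT libraries numbered 3 (20 and 44). The calls of Csrp1, Manea, Ikbip and Ccr7 ended in 18, 16, 15 and 12 of the alternatives, that of Ctse in 9, those of Hvcn1 and Fgfbp3 in 7, Dusp5 in 5, Ptpn7 in 4, Ephx1 in 2 and Slc40a1 in 1.

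The 1 h and 6 h calls between genotypes shared 14 genes, 6 higher and 8 lower at both times, where independent lists of these sizes would share 0.01 and 0.05. No gene was called in opposite directions. The shared genes with a symbol of a known gene were Fcmr, Ctse, Cxcr4, Rnpep, Mcm6, Klhl12, Ide, Fgfbp3 and Slc40a1 besides the immunoglobulin segments. Libraries of the same number and genotype deviated together across the times, so these overlaps are not independent. Called genes were in excess near Fcmr. Of 62 tested genes within 5 Mb of Fcmr, leaving Fcmr out, 12 (19.4%) were called at 1 h or 6 h, against 62 of 11770 elsewhere (0.53%; two-sided Fisher exact test over genes, p = 2.38e-15). The 12 genes were Map3k19, Mcm6 and Cxcr4 before Fcmr and Rassf5, Ctse, Dstyk, Klhl12, Ube2t, Ptpn7, Gm15445, Rnpep and Csrp1 after it, the farthest 3.05 Mb before and 4.85 Mb after. Of 18 tested genes between 5 and 10 Mb away 0 were called.

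**Figure D3:**
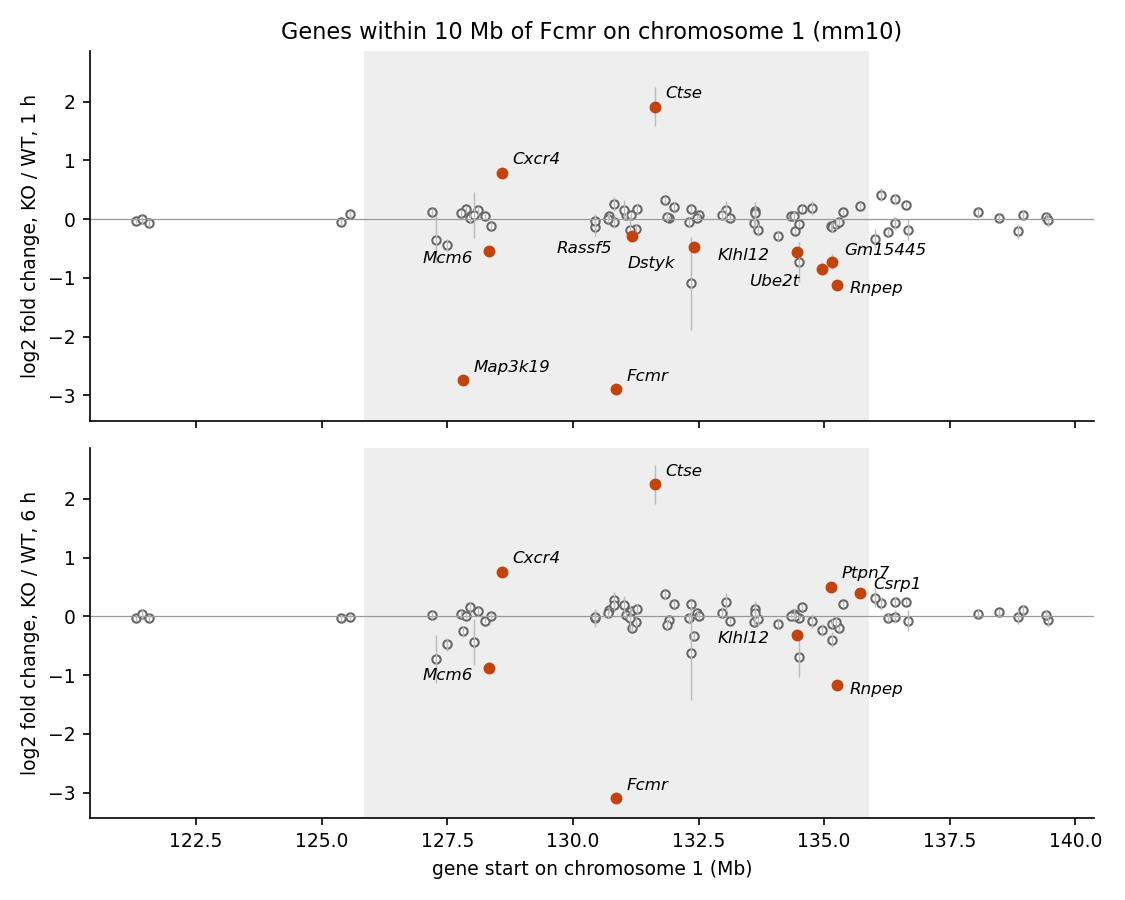
Log2 fold change of KO against WT (y axis) against gene start on chromosome 1 in Mb (x axis, mm10) for tested genes within 10 Mb of Fcmr, at 1 h above and 6 h below. Points are genes with their SE, filled and named where the adjusted p is under 0.05, and the grey band spans 5 Mb on each side of Fcmr.

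Immunoglobulin V segments were outside the rule for named genes and were singled out after their values were seen. Igkv5-39 stood at 7706 ± 4623 FPKM in KO and 310.6 ± 113 FPKM in WT cells at 1 h (SD, n = 3 each; log2 fold change 4.53, SE 0.52, adjusted p = 0.00333) and had the same log2 fold change of 4.53 at 6 h (adjusted p = 0.00675). Ighv11-2 was higher by 2.82 at 1 h and 2.99 at 6 h (adjusted p = 0.00626 and 0.00812) and Iglv2 by 1.25 and 1.09 (adjusted p = 0.009 and 0.0332). Igkv14-126, at 2.39 and 2.45, did not pass (adjusted p = 0.0614 and 0.101). Near-identical V segments can share reads, so single segment values are uncertain. Over V genes, same-number libraries of a genotype deviated together across the times (correlations of 0.853 to 0.867 in WT and 0.896 to 0.905 in KO). The values at 6 h are therefore not independent of those at 1 h. The fit took the spread from all 12 libraries as if independent, so these p-values may be too small.

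From 1 h to 6 h of stimulation, WT cells changed 9324 of 11841 genes (limma, adjusted p under 0.05), with 5865 higher and 3459 lower at 6 h, and KO cells 9292 genes, 5990 higher and 3302 lower. The largest rises of named genes in WT cells were those of Il2ra, the IL-2 receptor alpha chain (log2 fold change 3.78, SE 0.11), the nucleotide enzyme genes Dctd (3.62) and Dctpp1 (2.96), the folate transporter gene Slc19a1 (3.29), the branched-chain transaminase gene Bcat1 (3.27), Mreg (3.12), Rangrf (3.05) and the transcription factor gene Stat5a (2.91). In KO cells Dctd (3.86), Slc19a1 (3.58), Il2ra (3.44), Bcat1 (3.06), Mreg (3.05), Tfap4 (2.96), Dctpp1 (2.92) and the nucleoside transporter gene Slc29a2 (2.89) rose most. The immediate early genes Fosb (-6.93 in WT and -7.06 in KO), Nr4a2 (-5.16 and -4.83), Fos (-4.67 and -4.82) and Atf3 (-4.19 and -4.05) fell, as did Plk2 (-4.81 and -4.58) and the adhesion receptor gene Adgre5 (-3.96 and -3.99). Klf4 (-4.09) and Plaur (-4.07) in WT, and Cacna1i (-3.90) and Lmna (-3.90) in KO cells completed the named falls. The genotypes shared 5644 higher and 3129 lower genes, where independent lists would share 2967 and 964.6, and 2 genes were called in opposite directions. The fold changes correlated at r = 0.977 across genes, which are not independent replicates. Called genes split the 3 libraries of each time without overlap in 9053 (WT) and 9190 (KO) cases, and 78.95% and 82.48% of all genes did so, against 10% by chance.

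The median gene rose by 0.212 in WT and 0.218 in KO cells, and by 0.06 and 0.047 after quantile normalization, so list medians over time are given relative to the median gene. Immediate early genes fell most, with 35 of 38 lower in both genotypes (relative median -2.104 in WT and -1.914 in KO), 2 higher in WT and 1 higher in KO. Egr3 (-2.47 and -2.41) and Per1 (-3.03 and -2.91) were among them with Fosb and Nr4a2. MYC and ribosome biogenesis genes rose, 39 of 39 in both genotypes (relative medians 1.224 and 1.236), with the pyrimidine synthesis gene Cad at 2.28 and 2.35, Wdr12 at 2.06 and 2.12, and Mybbp1a at 1.75 and 1.77. Cholesterol synthesis genes rose, 23 of 24 in both (1.247 and 1.081), including Idi1 (2.40 and 2.18) and Lss (1.90 and 1.83). Of 34 genes of amino acid transport and tRNA charging 29 rose and 2 fell (1.271 and 1.252), with the tRNA synthetase genes Iars (2.00 and 2.00), Lars (1.91 and 1.96) and Eprs (1.24 and 1.24). Of 12 heat shock genes 11 rose (0.872 and 0.781), among them Hspa4 (1.01 and 0.98) and Hspd1 (2.40 and 2.47). Of 21 glycolysis genes 15 rose in both, with Pgk1 (1.36 and 1.49) and Ldha (1.62 and 1.72), while 6 fell in WT and 3 in KO, Slc2a1 (-1.48 and -1.47) among them. Of 32 G1/S genes 10 rose and 12 fell in WT and 11 rose and 11 fell in KO cells, with Cdk4 (1.93 and 1.99) and Cdca7 (2.36 and 2.53) rising.

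Receptor and presentation genes fell over the same interval. Of 34 BCR signalling components 25 fell in both genotypes (relative medians -1.087 and -1.016), including Cd79a (-1.95 and -1.83), Bank1 (-3.31 and -3.33) and the kinase gene Syk (-2.32 and -2.35), while 7 rose in WT and 8 in KO. Of 26 inhibitory receptors and phosphatases 19 fell in WT and 16 in KO (-0.893 and -0.865), with Siglecg (-2.32 and -2.16) and Cd22 (-2.19 and -1.98). Of 14 MHC class II genes 13 fell in WT and 12 in KO (-1.405 and -1.265), with H2-DMb2 at -2.06 and -1.75. Of 25 quiescence genes 21 fell in WT and 20 in KO (-1.163 and -1.074), including Tsc22d3 (-2.78 and -2.76) and Klf2 (-3.24 and -2.91). Of 21 NFAT responsive genes 15 fell in WT and 14 in KO (-1.035 and -1.091), and of 33 NF-kB target genes 16 and 17 fell and 7 rose (-0.317 and -0.483), with Nfkb1 rising (1.28 and 1.06) and Nfkbid falling (-1.67 and -1.99). Among activation markers 13 of 28 fell in WT and 14 in KO, such as Cd69 (-2.95 and -2.90), and 9 and 8 rose. In WT their median was 0.04 above 0 and their mean -0.295. Marginal zone markers fell for 11 of 19 in WT and 10 in KO, and rose for 3 and 6. Macrophage markers fell in both, 18 of 21 in WT and 16 in KO (-1.632 and -1.575), with C1qa at -3.46 and -3.21, as did 11 of 15 NK cell markers in WT and 10 in KO and all 6 platelet markers in both. Adjusted over the list alone these counts were unchanged for all lists named for this interval except 2 higher immediate early genes and 21 lower quiescence genes in KO and 19 and 17 lower macrophage markers in WT and KO.

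**Figure D4:**
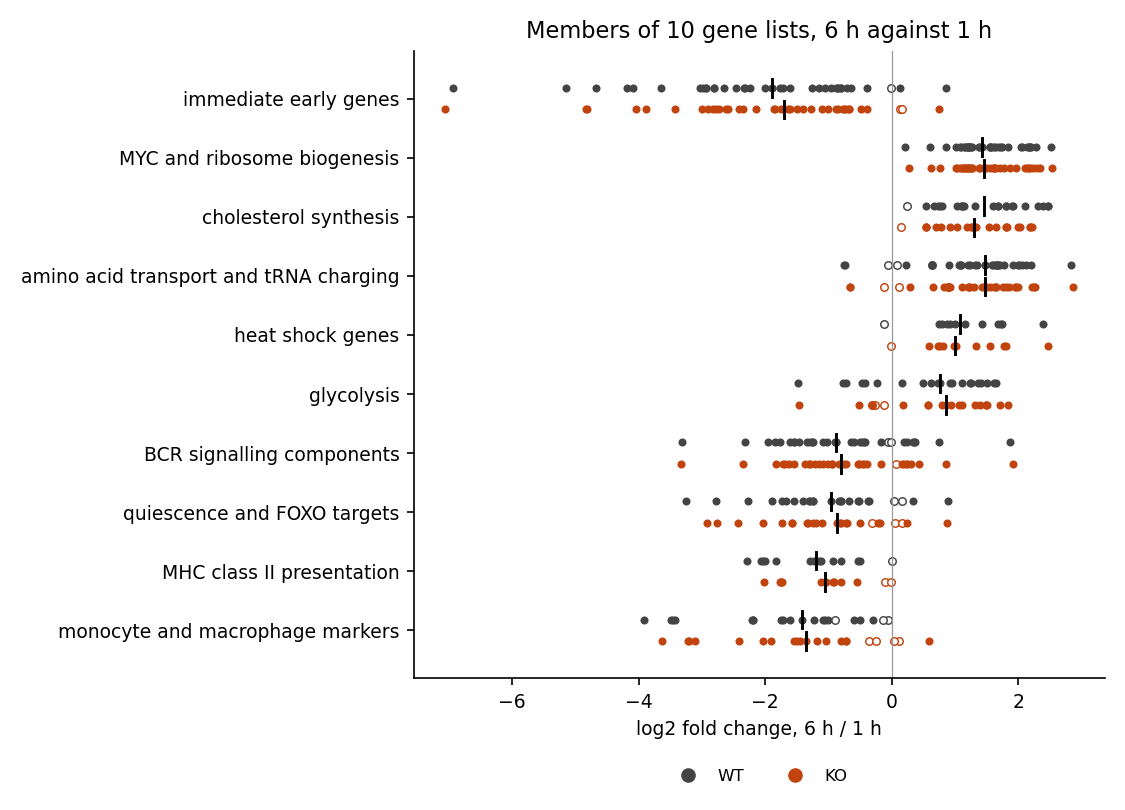
Log2 fold change from 1 h to 6 h (x axis) for each tested member of 10 gene lists (y axis), in WT and in KO cells. Points are genes, filled where the adjusted p is under 0.05, and black ticks are list medians, not set against the median gene, which for immediate early genes are -1.892 in WT and -1.696 in KO.

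With camera 26 lists passed over time in WT, 4 up and 22 down, and 25 in KO, 4 up and 21 down. None passed with an estimated correlation, where the smallest adjusted p was 0.14 in WT and 0.156 in KO cells. The lists up in both were MYC and ribosome biogenesis (camera adjusted p = 1.7e-09 in WT), cholesterol synthesis (1.75e-05), amino acid transport and tRNA charging (7.15e-06) and heat shock genes (0.0133), with 0.245, 0.245, 0.245 and 0.438 as the adjusted p with an estimated correlation. Immediate early genes (8.01e-15), BCR components (9.58e-07), MHC class II (1.04e-06) and quiescence genes (1.58e-07) were down, with 0.14, 0.14, 0.177 and 0.14 as the adjusted p with an estimated correlation. Glycolysis (adjusted p = 0.116) and G1/S (0.183) did not pass in WT. For changes of at least 1.5-fold the counts of genes were 5800 in WT and 5669 in KO.

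The change from 1 h to 6 h was compared between genotypes directly, and 3 genes differed (limma, adjusted p under 0.05), all with a higher value of the KO change. Map3k19 fell in WT from 6.28 to 0.21 FPKM and stood at 0.0832 and 0.0139 FPKM in KO cells (difference of log2 changes 2.49, SE 0.14, adjusted p = 3.3e-05). With KO levels of Map3k19 this low the difference was 3.74 at a pseudocount of 0.1 and 2.32 with voom, and passed in neither (adjusted p = 0.0923 and 1). Nebl, a protein of actin filaments, fell from 7.78 ± 0.152 to 0.331 ± 0.0438 FPKM in WT and from 3.89 ± 0.0639 to 0.31 ± 0.0315 FPKM in KO cells (SD, n = 3 each; 0.82, SE 0.08, adjusted p = 0.0074). Dph5, an enzyme of diphthamide synthesis, rose from 30.4 to 45.5 FPKM in WT and from 20.5 to 43.8 FPKM in KO cells (0.50, SE 0.06, adjusted p = 0.0359). No gene passed in the other direction (limma, 537 genes at an unadjusted p under 0.05 in either direction), where the smallest p were those of the adhesion receptor gene Cd44 (-0.33), Stt3b (-0.24), the cyclin gene Ccnd2 (-0.70), Kbtbd4 (-0.23) and Tnfrsf8 (-0.51). The change of Fcmr did not differ (-0.20, SE 0.07, adjusted p = 1). Of 19 marginal zone markers 0 were called (9 at an unadjusted p under 0.05) and 6 were higher adjusted over the list alone, with a median of 0.275 and Pik3r4 at 0.51, S1pr3 at 0.51, Myof at 0.57 and Cd1d1 at 0.56 (camera adjusted p = 2.73e-10, adjusted p = 0.0432 with an estimated correlation). In all, 8 lists passed camera, 5 up and 3 down, and that of the marginal zone did so with an estimated correlation. With the pairing of libraries of the same genotype and number as a block 1 gene was called, and the adjusted p of Nebl became 0.207 and that of Dph5 0.269. The count was also 1 without WT replicate 2, WT replicate 3 or KO replicate 1 of 1 h, 21 with no filter and 0 at a pseudocount of 0.1 (limma, 530 genes at an unadjusted p under 0.05).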

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

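All tests of explanations in this part were chosen only after the result was seen. For reads moved between near-identical V segments alone, the prediction was written before its test was run. Groups of 3 libraries were not searched systematically for single deviating libraries, and those named in the text were singled out after their values were seen.

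The genotype effect differed between 1 h and 6 h, by limma's test of that difference, for Map3k19 (effect at 6 h less that at 1 h, 2.49 on the log2 scale), Nebl (0.82) and Dph5 (0.50). No gene was called at a pseudocount of 0.1, at a mean of at least 5 FPKM or with voom (limma, 530, 347 and 503 at an unadjusted p under 0.05). With the paired block of genotype and number the adjusted p of Nebl was 0.207 and that of Dph5 0.269, and the calls of Map3k19, Nebl and Dph5 ended in 2 of 26, 9 of 26 and 19 of 27 alternatives. That of Nebl ended without WT_1h replicate 2 or 3 or KO_1h replicate 1 (adjusted p = 0.0627, 0.0522 and 0.053), and that of Dph5 in all cases of 1 library left out except KO_1h replicate 3 (adjusted p = 0.0659 to 0.195 where it ended). By camera it differed for 8 lists, with medians of 0.129 for immediate early genes, -0.079 for NF-kB target genes, 0.098 for glycolysis, -0.091 for cholesterol synthesis, -0.105 for ER stress and the unfolded protein response, 0.175 for MHC class II presentation, 0.275 for marginal zone B cell markers and 0.251 for macrophage markers. At 6 h some macrophage transcripts stood near 1 FPKM (C1qa 1.39 in WT and 0.849 in KO, C1qc 1.43 and 0.731). At such levels the pseudocount of 1 shrinks a log2 fold change. The median of 0.251 therefore does not show that the macrophage difference became smaller with time. With an estimated correlation the adjusted p was 0.0432 for marginal zone markers, 0.433 for NF-kB target genes, 0.555 for macrophage markers and 0.878 for the other 5 lists. The camera call ended without 1 library for immediate early genes (WT_1h replicate 3, KO_1h replicate 3 and WT_6h replicate 3, adjusted p = 0.649, 0.137 and 0.0767), glycolysis (WT_1h replicates 1 and 2, KO_1h replicate 2, WT_6h replicate 3 and KO_6h replicate 1, 0.362, 0.0501, 0.104, 0.273 and 0.0938) and cholesterol synthesis (WT_1h replicate 1, 0.0847). It also ended for ER stress and the unfolded protein response (WT_1h replicate 3, KO_1h replicate 3, WT_6h replicates 1 and 2 and KO_6h replicate 2, 0.0976, 0.363, 0.0675, 0.288 and 0.114) and MHC class II presentation (WT_1h replicates 2 and 3, WT_6h replicate 3 and KO_6h replicate 3, 0.0557, 0.0713, 0.17 and 0.0649). Same-number libraries of a genotype deviated together across the times. With these kept together there are 10 splits of the libraries by genotype, too few for a share under 0.05, and 1 of them gave at least 3 genes (3, highest other 1) and 4 at least 8 lists (8, highest other 11). When genotypes were regrouped at random within each time, which parts these pairs, 14 of 100 splits gave at least 3 genes (highest 123) and 76 of 100 at least 8 lists (highest 19). What sets the split with 123 genes apart was not tested.

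Called genes between KO and WT were in excess near Fcmr on chromosome 1, with 12 within 5 Mb and 62 elsewhere. An effect of the missing receptor without regard to position, as the whole account, was argued against by the excess of called genes within 5 Mb (Fisher exact test over genes, p = 2.38e-15). The window was set after the values were seen, so this p-value restates the pattern. It says nothing on the 62 called genes elsewhere, for which an effect of the missing receptor stayed open. A local effect of the altered allele within 1 Mb as the whole account was argued against by the excess between 1 and 5 Mb (Fisher exact test, p = 2.1e-13). DNA of another strain carried along with the knockout allele predicts an excess on both sides, which was found on the weaker side too (3 of 19 genes before Fcmr, Fisher exact test, p = 0.000212), and it is a candidate explanation for the 12 genes near Fcmr, Ctse, Cxcr4 and Mcm6 included. The strain in which the allele was made is not given in the sources used here, and neighbouring genes are not independent. How much of the difference of each gene comes from this stayed open.

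Marginal zone and macrophage genes were lower in KO at 1 h. The authors' scaling of whole libraries as the whole account was argued against for the marginal zone list. The median gene at 1 h stood at -0.011 and this list at -0.366, and the list stayed at -0.341 under quantile normalization. With so small a shift of the median gene, quantile normalization alone was a weak test. The macrophage list was not tested in this way. Fewer marginal zone B cells in the KO samples stayed open, since the median at 6 h was -0.034 and the change differed by genotype, yet transcripts of these cells change in culture. A smaller share of all other cell types stayed open too, since the macrophage list less the T cell list was lower in KO by 0.297 on average (KO 1.208 ± 0.175, WT 1.505 ± 0.205; SD, n = 3 each), yet the libraries met at 1.314, the highest KO and the lowest WT value. Of the markers 3 of 19 marginal zone and 0 of 21 macrophage genes were in another list. This does not show which cells the transcripts came from, and a share of macrophages in the marginal zone shift was not tested. Abundant macrophage transcripts at 1 h were Lyz2 (WT 186 ± 43.6, KO 123 ± 39.7 FPKM) and C1qa (25.4 ± 3.35 and 16.2 ± 2.18 FPKM), although the cells were purified as B cells.

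Igkv5-39, Ighv11-2 and Iglv2 were higher in KO at both times. The lowest KO library exceeded the highest WT library by at least 1.75-fold for each segment at both times, so no single KO library carried the difference. The segments were picked from called genes, whose genotypes overlapped in none, and same-number libraries of both times deviated together. This separation is therefore no test of expanded clones in single animals, which stayed open. Reads moved between near-identical segments were not tested for Ighv11-2 and Iglv2 and were argued against for Igkv5-39 by the summed Igkv5 family, whose lowest KO library exceeded the highest WT library by at least 5.08-fold. More B-1 cells in the KO samples, or a different set of V alleles, may account for the pattern, and the B-1 marker list did not decide. At 1 h its median was 0.083 with 0 of 16 called (camera adjusted p = 0.0573, adjusted p = 0.365 with an estimated correlation). At 6 h the median was 0.106 (camera adjusted p = 0.179). V alleles were not tested.

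The 6 libraries of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. At 1 h 2 of 10 splits gave as many genes (62, highest other 74) and 2 of 10 as many lists (16, highest other 18), and the split with 74 genes set WT replicates 1 and 2 with KO replicate 1 against the others. At 6 h 1 of 10 gave as many genes (27, highest other 0) and 3 of 10 as many lists (14, highest other 15). Over time 1 of 10 gave as many genes in WT (9324, highest other 0) and in KO (9292, highest other 0), and 1 of 10 as many lists in WT (26, highest other 23) and 3 of 10 in KO (25, highest other 27). All other splits over time mix libraries of 1 h and 6 h in a group, which widens the spread of the refit. Their counts of 0 genes were thus to be foreseen and lend no support. Of these 10 splits 4 part all pairs of same-number libraries, the real one among them, and the other 3 gave at most 0 genes in either genotype, 23 lists in WT and 26 in KO.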

How the results depend on the processing

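Fcmr stayed lower in KO under all alternatives, from -2.66 to -2.93 at 1 h and -3.03 to -3.27 at 6 h. Over the named genes 13915 values kept direction and side of the threshold, 185 gained a call, 225 lost one and 5 reversed, and over lists 2297 kept both, 241 lost the call and 2 reversed. The cause was not tested except where an alternative tests fewer genes or uses fewer libraries.

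With a threshold of 1.5-fold 40 (1 h), 15 (6 h), 5800 (time in WT) and 5669 (time in KO) genes were called. With an estimated correlation 2, 0, 0 and 0 lists passed camera, and 1 for the difference between genotypes; fry gave 5, 4, 27, 28 and 1. At 1 h 115 genes were called with no filter, 32 at a mean of at least 5 FPKM, 21 from the 6 compared libraries, 191 without both WT libraries numbered 3 and 106 with voom on recovered fragments. At 6 h 10 were called from the 6 compared libraries, 64 without both WT libraries numbered 3, 1948 with array weights and 345 with weights fitted gene by gene. The default fit of the weights did not converge and gave WT replicate 1 of 6 h a weight of 14.6 (3.61 gene by gene), so 1948 is not a reliable count. The last 4 kinds of alternative named in the methods (weights gene by gene, both WT libraries numbered 3 left out, the mouse as a random effect, voom) were chosen after seeing the data.

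For the difference between genotypes the 3 genes became 0 at a pseudocount of 0.1 (limma, 530 at an unadjusted p under 0.05), 0 at a mean of at least 5 FPKM (347) and 0 with voom (503), 1 with TPM rescaling, 1 without both WT libraries numbered 3, 5 with the mouse as a random effect, 5 and 12 with weights fitted gene by gene and by default, and 21 with no filter.

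Leaving out 1 library gave 30 to 142 genes at 1 h (30 without KO_1h replicate 1, 31 and 39 without WT_1h replicates 2 and 1, 142 without WT_1h replicate 3), 12 to 30 at 6 h (12 and 17 without WT_6h replicates 1 and 2, 16, 14 and 15 without KO_6h replicates 1, 2 and 3), 9030 to 9315 over time in WT, 8893 to 9481 in KO and 1 to 3 for the difference (1 without WT_1h replicate 2 or 3 or KO_1h replicate 1). Its lists numbered 5 (without WT_6h replicate 3) to 11, and 12 to 17 lists passed at 1 h and at 6 h. The MYC list at 1 h had an adjusted p of 2.16e-05 to 0.643 and reversed without WT_1h replicate 1. The interferon list at 6 h had 1.45e-13 to 1 and reversed without KO_6h replicate 1. Without 1 library a group holds 2, assumed to vary like the others.

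The change of Fcmr over time in WT (0.04) was -0.02 with TPM rescaling, -0.08 without immunoglobulin and mitochondrial genes, -0.03 and -0.01 with the 2 kinds of weights, and 0.00 to 0.07 with 1 library left out, and passed in none of these that reversed it.

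With the paired block of genotype and number 9681 genes were called over time in WT, 9659 in KO and 1 for the difference (Nebl adjusted p = 0.207, Dph5 0.269), with 25, 25 and 10 lists. It ended the camera call of activation markers in WT (0.056) and of interferon genes in KO (0.0524), and cannot estimate KO against WT. The block of number alone, which pairs no WT with KO library, gave 53, 25, 9432, 9362 and 1 genes and 16, 15, 26, 26 and 8 lists.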

Other observations

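Fgfbp3 and Ide, 2 genes near each other on chromosome 19 that were singled out after their values were seen, were lower in KO at both times. Fgfbp3 changed by -0.70 at 1 h and -0.79 at 6 h and Ide by -0.84 at both, all called (mm10, 36917550 to 37337852). Between them Btaf1 (-0.33 and -0.33) and March5 (-0.15 and -0.10) did not pass, and outside them Tnks2 (0.01 and 0.07), Kif11 (-0.39 and -0.18), Hhex (0.12 and 0.18) and Exoc6 (-0.06 and 0.01) did not pass either. Farther out Myof (37899036 to 38043577) was called at 1 h (-0.67) and did not pass at 6 h (-0.09). No explanation and no excess of called genes was tested for this region.

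Other V segments were looked at in the same way. The lowest KO library stood at 3.29 and 2.7 times the highest WT library for Igkv14-126 at 1 h and 6 h, at 1.38 and 1.96 times for Ighv12-3, and at 1.02 and 0.927 times for Igkv4-91. The other 4 genes of the Igkv5 family summed to 407 ± 17.4 FPKM in KO and 389 ± 92.5 FPKM in WT at 1 h (SD, n = 3 each). Immunoglobulin genes took 3.38% to 12.06% of the summed FPKM of a library and mitochondrially encoded genes 4.06% to 6.24%. The mitochondrial transcript mt-Co2 stood at 20.9 FPKM in WT replicate 2 of 6 h and at 0.64 to 2.12 FPKM in the other 11 libraries. Hbb-bs, a haemoglobin gene, stood at 1230, 1130 and 351 FPKM in WT replicates 1, 2 and 3 of 1 h and at 818, 328 and 519 FPKM in the KO replicates.

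The 75 genes called at 1 h or 6 h comprised Fcmr, 12 genes within 5 Mb of it, 5 immunoglobulin genes, 7 members of the macrophage list and 50 others. Of the 14 called at both times 4 were among those others.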
